A study of Mus musculus with 10 samples.

How the data were processed

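The series holds whole-genome bisulfite libraries of mouse embryos of the B6D2F1 strain, per the labels, 2 for each of the 8-cell embryo, ICM, TE, proximal epiblast and ExE. Libraries were made with the Accel-NGS bisulfite kit, per the labels' protocols. ICM and TE were dissected from matched blastocysts by laser, and the epiblast and ExE came from conceptuses cut along the embryonic axis, per the labels' protocols. The labels do not say how many embryos a library holds or whether the replicates came from separate collections, so that p-values measure the spread between these libraries, which may be technical.

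The authors deposited 1 table of CpGs per library. Its columns hold the position, the methylation level in whole percent with the number of reads in brackets, and a score from the authors that is the same level per mille of reads. The build is mm9, per the submitters' processing notes. The aligner, the methylation caller, read filters and the treatment of PCR duplicates are not given in the sources used here. CpGs with fewer than 5 reads were not listed in any of the 10 tables. The number of methylated reads was recovered as the score times the reads, rounded. It gave back the score in every row. Above 1000 reads a per mille score no longer fixes the number exactly.

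Everything else was computed from these reads. CpG positions were the union of those listed in any library, since no genome of the build was used here. CpG-dense regions were made by merging windows of 300 bp that held at least 15 CpGs; they are not annotated CpG islands. Tiles were non-overlapping segments of 1 kb. Reads were summed over the CpGs of a region, and a region was tested when each library had at least 20 reads and 3 CpGs there. This left 37696 of 57858 CpG-dense regions (median 274 reads per region and library) and 766277 of 2525852 tiles (median 110 reads). Filtering on all 10 libraries ties the set tested to the shallow 8-cell libraries.

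Each region was fitted with a quasi-binomial logistic model with 1 mean per group over all 10 libraries, which leaves 5 residual degrees of freedom. The dispersion was moderated across regions by the method of limma's squeezeVar and kept at 1 or above. The code was checked against limma 3.58.1, which gave the same prior. The prior dispersion was 3.47 with 8.29 degrees of freedom in CpG-dense regions and 2.09 with 23.2 in tiles. A read that covers several CpGs is counted at each of them, so that a dispersion above 1 does not by itself show a difference between libraries. Pairs of groups were compared by an F test, and the difference of differences by a Wald test on the scale of the level. P-values were adjusted by Benjamini and Hochberg over regions, for each of 6 comparisons separately. Calls needed an adjusted p under 0.05 and a difference of at least 10 percentage points between the means of the library levels. Values are given as mean ± SD of the 2 library levels. The rule for named regions, fixed before the data were examined, was the 2 largest differences in each direction per comparison, by position, among called CpG-dense regions in which both libraries of one group lay above both of the other, for the case that no annotation of the build was given. A list of genes fixed at the same time was not tested, for the same reason.

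The test was run on simulated data, with reads drawn for the real regions from the real depths and dispersion. For ExE minus epiblast in CpG-dense regions it recovered 44.0% of simulated changes of 15 points and 88.0% of those of 30 points, and 4.35% of its calls were false. Over all comparisons the false share ran from 1.72% to 14.3%, and it was 12.8% for the difference of differences, 8.49% for TE minus ICM in CpG-dense regions and 10.1% for ExE minus epiblast in tiles. For most comparisons it was thus above the nominal 5%, but it rested on only 1 to 12 false calls in each and is imprecise. Each simulation changed 100 regions by 15 points and 100 by 30 points, among 37696 CpG-dense regions or 100000 tiles. Most real comparisons called a far larger share, so that the recovered and false shares may not carry over to them. Global levels were given as the mean over listed CpGs and as the level weighted by reads, without a test. Bins of CpG density used tiles with at least 20 reads in every library. Classes of single CpGs used those with at least 10 reads. The classes by region size, the levels of called sets in other groups, the overlap between lineages with its background, and the levels around regions were chosen after the data were seen.

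Mitochondrial CpGs were left out of all tests and used as a check on bisulfite conversion, since mitochondrial DNA is expected to carry little CpG methylation. They showed 0.303% to 1.28% methylated reads, the highest in ExE replicate 2 with an exact (Clopper-Pearson) 95% interval of 1.26% to 1.30%. Such intervals cover counting error only, because the reads carry no molecular identifiers.

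The alternatives, listed before the data were examined, were other minimum depths, other minimum differences, leaving out each replicate, limma on mean CpG levels, a spread from the compared groups only, the replicate number as a block, reads thinned to the shallowest library, other window and tile definitions, and autosomes only. Leaving out CpGs above 250 reads, and leaving out the 8-cell libraries, were added after seeing the data. A planned count test from another package was not run. The tables hold levels and depths, not columns of counts, although the counts recovered from them for the main test could have been used. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.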

Results

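Whole-genome bisulfite sequencing was carried out on mouse embryos before and after implantation, and the methylation level of each CpG was read from the share of reads that stayed cytosine after bisulfite treatment. The 10 libraries fell into 5 groups of 2. These were 8-cell embryos before compaction (E2.25), the inner cell mass (ICM) and the trophectoderm (TE) of the blastocyst (E3.5), and the proximal epiblast and the extraembryonic ectoderm (ExE) of the early post-implantation conceptus (E6.5). The ICM is the part of the blastocyst that gives rise to the epiblast and so to the embryo proper. The TE is its outer layer, from which the ExE and later parts of the placenta descend. The labels set the ExE at the centre of the series, so that the comparison of ExE with epiblast is the main one and the earlier groups give the starting levels of both lineages.

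Between 7.69 M and 20.5 M nuclear CpGs (M, mega) were listed per library, each with at least 5 reads, and 4.34 M of the 21.1 M CpGs seen in any library were listed in all 10. Depth was unequal. The 8-cell libraries held 127 M and 196 M reads at nuclear CpGs and the epiblast libraries 289 M and 368 M. Leaving out CpGs covered by more than 250 reads, the mean depth was 8.52 to 15.3 reads per listed CpG. CpGs with fewer than 5 reads are not listed, so that this range understates how unequal the depth was. The reads at CpGs up to 250 reads were 65.5 M in 8-cell replicate 1 and 313 M in epiblast replicate 2. The CpGs above 250 reads, or pile-ups, took 48.5% and 38.0% of the reads of the 8-cell libraries and 15.0% of those of each epiblast library. Positions are in mm9 and are counted from 1. No annotation of that build was used here, so that regions are named by position and not by gene.

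The 5 groups differed widely in their global methylation level. The mean level over CpGs was 48.2% ± 1.53 (SD, n = 2) in 8-cell embryos, 22.0% ± 0.98 in the ICM and 18.97% ± 0.375 in the TE. It was 78.8% ± 0.152 in the epiblast and 53.1% ± 1.53 in the ExE. The epiblast lay 56.8 points above the ICM (SE 0.701), and the ExE lay 34.1 points above the TE (SE 1.11). The ExE lay below the epiblast, with a difference of ExE minus epiblast of -25.7 points (SE 1.09). In each of the 6 pairs of groups compared, both libraries of one group lay above both of the other. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333, so that these differences are set against the spread between libraries only. Weighted by reads, the levels were 41.4% ± 1.97, 24.5% ± 0.584, 21.5% ± 0.353, 80.5% ± 0.228 and 54.0% ± 1.19 in the order of the groups. Without the pile-ups the weighted level of the 8-cell embryos was 49.7% ± 1.12.

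**Figure D1:**
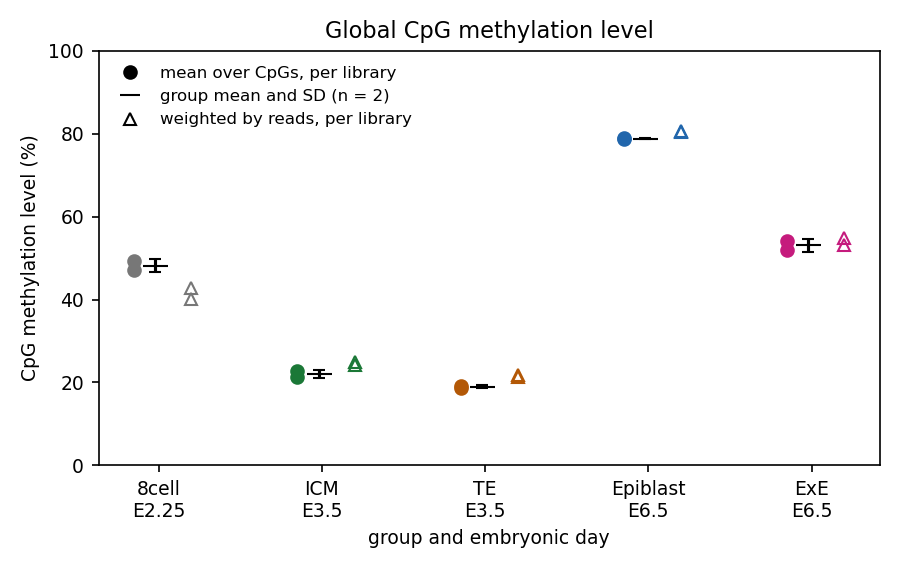
Global CpG methylation level per library (y axis, percent) by group and embryonic day (x axis). Filled circles are the mean over CpGs of each library, horizontal bars with whiskers the group mean and SD (n = 2), and open triangles the level weighted by reads. The mean over CpGs runs from 18.97% in the TE to 78.8% in the epiblast, with the ExE at 53.1%.

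The distribution of single CpGs differed as well. Among CpGs with at least 10 reads, 64.2% ± 1.17 lay above 80% in the epiblast and 4.54% ± 0.421 lay below 20%. In the ExE, only 18.5% ± 1.22 lay above 80%, and 70.7% ± 0.609 were between 20% and 80%. In the ICM and the TE, 48.3% ± 0.0108 and 56.0% ± 0.246 of CpGs lay below 20%.

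Between the 8-cell stage and the blastocyst, methylation fell in most of the tested tiles in both lineages. Of 766277 tiles of 1 kb, 607200 fell and 71 rose from 8-cell embryos to the ICM, and 651975 fell and 31 rose to the TE (quasi-binomial model, adjusted p under 0.05 and at least 10 points). CpG-dense regions, defined as merged windows of 300 bp with at least 15 CpGs, numbered 37696 after filtering and had a median of 30 CpGs and 525 bp. In these, 16889 fell and 12 rose to the ICM, with a median difference of -13.1 points. To the TE, 20726 fell and 7 rose, with a median difference of -16.8 points. The region with the largest fall to the ICM lay on chromosome 2 from 5004400 to 5004867, at 84.3% ± 0.952 in 8-cell embryos and 9.58% ± 5.02 in the ICM (adjusted p = 1.1e-05). It was again at 94.2% ± 1.47 in the epiblast. A region on chromosome 4 from 85844383 to 85844782 went from 89.2% ± 15.3 to 17.3% ± 13.2 (adjusted p = 9.5e-04). For the TE the largest falls were on chromosome 6 from 124781995 to 124782261, from 93.9% ± 0.0 to 8.29% ± 7.31 (adjusted p = 7.5e-05), and on chromosome 11 from 62700926 to 62701257, from 85.5% ± 6.75 to 8.89% ± 11.5 (adjusted p = 1.9e-04).

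The few gains at this step were less certain. A region of 26 CpGs on chromosome 4 from 150253888 to 150254298 stood at 19.3% ± 3.75 in 8-cell embryos, 45.4% ± 7.17 in the ICM and 56.2% ± 8.29 in the TE. Its gain passed the test in both comparisons (adjusted p = 0.023 for the ICM and 0.0037 for the TE), but without 8-cell replicate 2 the adjusted p was 0.18 for the ICM and 0.066 for the TE, and without ICM replicate 1 it was 0.13 for the ICM. On chromosome 12 from 81269160 to 81269801 the level was 36.1% ± 19.6 in 8-cell embryos and 59.6% ± 9.84 in the ICM (adjusted p = 0.023). That call was lost without 8-cell replicate 2 (adjusted p = 0.76), without ICM replicate 1 (0.12) and with limma on mean CpG levels (0.16). On chromosome 10 from 52116287 to 52116418 the level was 10.3% ± 8.24 in 8-cell embryos and 29.4% ± 7.85 in the TE (adjusted p = 0.044). That call was lost without 8-cell replicate 1 (0.2), without TE replicate 1 (0.15), with the spread of the compared groups only (0.054), with limma (0.077), and with a minimum of 20 points, since its difference was 19.1 points.

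The ICM and the TE, the first lineages to separate, differed little. Over CpGs the TE was slightly lower, at TE minus ICM of -3.004 points (SE 0.742), with both TE libraries below both ICM libraries. In CpG-dense regions 1 region was lower in the TE and 0 were higher with the quasi-binomial model. With the replicate number as a block in that model, and with limma on mean CpG levels, 0 were called in either direction. At an unadjusted p under 0.05, 3784 regions differed where chance gives 1885, and of those with at least 10 points, 2469 were lower and 219 higher in the TE. The called region lay on chromosome 13 from 42190022 to 42190801 and held 44 CpGs. It was at 81.2% ± 5.31 in the ICM and 57.5% ± 0.164 in the TE (adjusted p = 0.045). Its level was 97.8% ± 0.58 in 8-cell embryos and 93.9% ± 1.17 in the ExE. Its call was lost without ICM replicate 2 (adjusted p = 0.12), TE replicate 1 (0.2) or TE replicate 2 (0.13), with a minimum of 50 reads and 5 CpGs per library (0.052), with the spread of the compared groups only (0.18) and with limma (0.12). Among 1 kb tiles, 300 were lower and 13 higher in the TE with the quasi-binomial model, while limma on mean CpG levels called 0 tiles. The lower tiles held a median of 27 CpGs against 11 for all tiles, and their median levels were 78.7% in 8-cell embryos, 59.3% in the ICM and 35.01% in the TE. The total of 313 tiles depended on single libraries, with 186 and 620 without ICM replicate 1 and 2, and 68 and 579 without TE replicate 1 and 2. Simulated differences of 30 points between TE and ICM were called in 71.0% of CpG-dense regions and 47.0% of tiles, and those of 15 points in 26.0% and 10.0%.

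From the ICM to the epiblast, methylation rose in nearly all tested tiles. Of the 1 kb tiles, 747653 rose and 906 fell, with a median difference of 61.5 points. CpG-dense regions rose in 24895 cases and fell in 505. The largest gains were on chromosome 8 from 120330409 to 120330684, where the level was 0.0% in both ICM libraries and 97.0% ± 1.82 in the epiblast (adjusted p = 2.1e-07), and on chromosome 3 from 151939478 to 151939785, from 0.485% ± 0.687 to 97.0% ± 1.71 (adjusted p = 3.0e-08). The regions that fell had a median of 47 CpGs. Their median level was 24.1% in the ICM and 3.05% in the epiblast. In the groups that did not enter this comparison, it was 44.0% in 8-cell embryos, 19.1% in the TE and 9.35% in the ExE. The largest falls were on chromosome 11 from 101037461 to 101037907, from 62.9% ± 3.91 to 2.20% ± 1.67 (adjusted p = 7.6e-07), and on chromosome 11 from 117721904 to 117722389, from 58.7% ± 4.603 to 8.01% ± 3.47 (adjusted p = 2.0e-05). In the ExE these regions were at 34.3% ± 0.924 and 39.1% ± 10.1.

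From the TE to the ExE, methylation also rose widely, by smaller amounts. Of the tiles, 695492 rose and 667 fell, with a median difference of 38.0 points, and of the CpG-dense regions, 23393 rose and 289 fell. The gains were largest on chromosome 13 from 55262580 to 55262894, from 0.637% ± 0.901 in the TE to 94.2% ± 0.907 in the ExE (adjusted p = 2.4e-07), and on chromosome 3 from 53281332 to 53281818, from 0.493% ± 0.697 to 92.3% ± 1.76 (adjusted p = 8.9e-08). Both were also above 90% in the epiblast, at 91.7% ± 3.66 and 90.9% ± 2.79. Among the falls, a region of 42 CpGs on chromosome 6 from 83036238 to 83036995 went from 58.5% ± 9.52 to 17.5% ± 2.34 (adjusted p = 8.3e-05). The largest fall by size, on chromosome 7 from 19985221 to 19985526, rested on TE libraries that disagreed, at 62.3% ± 48.3 against 20.8% ± 0.291 in the ExE (adjusted p = 0.014). Without TE replicate 1 its difference was -7.33 points (adjusted p = 0.71), and its call was also lost without ExE replicate 1 (adjusted p = 0.062) and with limma on mean CpG levels (0.17).

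The regions that lost methylation over implantation overlapped between the lineages. Among 21911 CpG-dense regions that stood at 10% or more in both the ICM and the TE and so could fall by 10 points, 436 fell from ICM to epiblast and 262 from TE to ExE. Of these, 186 fell in both, where independent lists would share 5.21 (Fisher's exact test, two-sided p = 3.4e-270, with regions taken as independent). The background was not matched on CpG number or starting level. All 505 regions that fell from ICM to epiblast held a median of 47 CpGs and all 289 from TE to ExE 53, against 30 in all tested. The overlap can thus reflect the kind of region shared by both lists. The 2 comparisons shared no library, although all 10 libraries shared the estimate of the spread. They may still share embryos, since ICM and TE came from matched blastocysts, and epiblast and ExE from conceptuses that were cut.

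The ExE and the epiblast differed in opposite directions in different parts of the genome. Of 766277 tiles, 608689 were lower and 6775 higher in the ExE. In CpG-dense regions 14041 were lower and 1646 were higher in the ExE. Without epiblast replicate 2 the number of lower regions was 9040, and that of higher regions 1361. The gap narrowed with CpG density. In tiles of 5 to 9 CpGs the mean level was 83.9% ± 0.258 in the epiblast and 54.6% ± 1.76 in the ExE. In tiles of 20 to 29 CpGs it was 77.9% ± 0.0681 and 61.3% ± 0.742, and in tiles of 60 to 79 CpGs 11.5% ± 0.192 and 10.1% ± 0.218. From 80 CpGs per kb on, the ExE was no longer below the epiblast, at 2.79% ± 0.133 against 2.51% ± 0.0025 in tiles of 80 to 99 CpGs, and at 1.88% ± 0.183 against 1.80% ± 0.0718 in those of 100 or more. The last difference was smaller than the SD between the ExE libraries. With tiles of 5 kb the ExE was first above the epiblast in the bin that starts at 60 CpGs per kb. By size of the CpG-dense region, the share called lower in the ExE was 54.8% at 15 to 19 CpGs and 2.83% at 120 or more. The mean epiblast level in these classes was 77.8% and 5.72%, so that many large regions stood too low for a fall of 10 points. The share called higher was 2.77% and 5.78%, with 5.50% at 50 to 79 CpGs and 4.77% at 80 to 119.

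**Figure D2:**
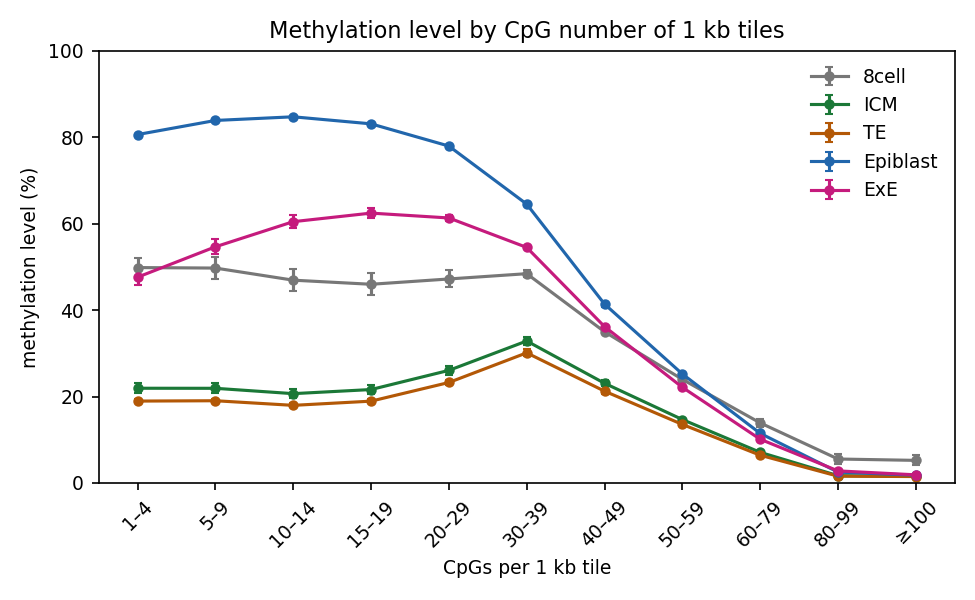
Mean methylation level (y axis, percent) of 1 kb tiles by the number of CpGs they hold (x axis), for the 5 groups. Points are group means and whiskers the SD between libraries (n = 2). The epiblast lies above the ExE from 83.9% against 54.6% at 5 to 9 CpGs down to 11.5% against 10.1% at 60 to 79 CpGs, and both are under 3% from 80 CpGs on.

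Most of the 1646 regions that were higher in the ExE stood at low levels in the earlier groups, but not all did. They held a median of 35 CpGs. Their median level was 24.3% in the ExE and 3.69% in the epiblast, the 2 groups by which they were chosen. In the groups that did not enter the comparison, it was 4.58% in 8-cell embryos, 1.52% in the ICM and 1.39% in the TE. Below 10% stood 1046 of them in 8-cell embryos, 1292 in the ICM and 1306 in the TE. At 20% or more in the ICM stood 269, and 175 were called lower in the epiblast than in the ICM. In 894 of the 1646 all 4 other groups were below 10%. Inside the 1646 regions the mean level was 15.6% ± 1.31 in 8-cell embryos, 7.55% ± 0.689 in the ICM and 6.31% ± 0.536 in the TE. In regions below 20% in the epiblast with no called difference, it was lower, at 6.02% ± 1.06, 1.775% ± 0.0283 and 1.64% ± 0.170. The 2 sets were not matched, since only 1402 of the 1646 were below 20% in the epiblast. These means pool all CpGs, so that a minority of methylated regions can raise them above the medians. Levels of the 1646 regions in the ExE were seldom high, with 214 above 50% and 42 above 80%. The largest difference was on chromosome 3 from 127248959 to 127249252 (16 CpGs), at 82.1% ± 3.798 in the ExE and 3.43% ± 2.64 in the epiblast (adjusted p = 3.0e-06), with 61.6% ± 0.383 in 8-cell embryos. The next was on chromosome 7 from 140951041 to 140951812 (35 CpGs), at 73.0% ± 6.78 and 7.13% ± 0.107 (adjusted p = 7.0e-07). Its level was 34.75% ± 4.85 in 8-cell embryos, 4.36% ± 0.478 in the ICM and 3.19% ± 1.74 in the TE. These regions had 21 to 272 and 55 to 722 reads per library.

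The 14041 regions that were lower in the ExE were of another kind. They held a median of 23 CpGs and stood at a median of 88.3% in the epiblast and 67.2% in the ExE, after 41.1% in the ICM and 36.8% in the TE. The largest differences were on chromosome 2 from 165686982 to 165687491, at 9.46% ± 4.18 in the ExE and 87.1% ± 2.52 in the epiblast (adjusted p = 1.4e-06), and on chromosome 3 from 84267952 to 84268281, at 15.4% ± 0.197 and 89.9% ± 0.771 (adjusted p = 3.4e-06). The second of these was at or below 4.03% ± 2.87 in 8-cell embryos, the ICM and the TE.

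**Figure D3:**
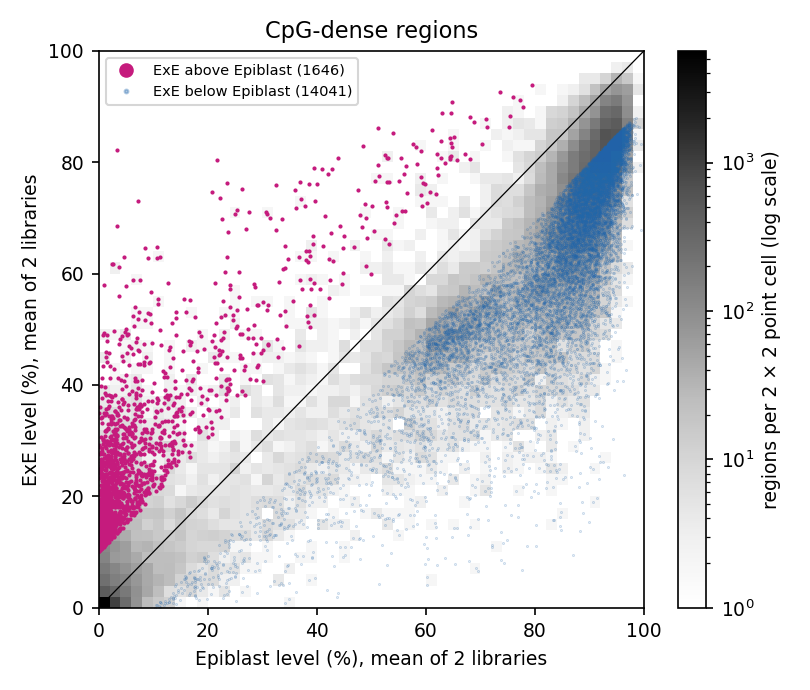
Methylation level of 37696 CpG-dense regions in the epiblast (x axis, percent, mean of 2 libraries) and the ExE (y axis, percent, mean of 2 libraries). Grey cells give the number of regions on a log scale, large magenta points the 1646 regions called higher in the ExE, small blue points the 14041 called lower, and the line marks equal levels. Most of the magenta points lie at the left edge, where the epiblast is below 10%.

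Whether the change over implantation differed between the lineages was tested by the difference of differences, ExE minus TE less epiblast minus ICM. It was called positive in 1391 CpG-dense regions and negative in 4414 (Wald test, adjusted p under 0.05 and at least 10 points). Called or not, it was negative in 71.6% of the 37696 regions, with a median of -3.55 points. The regions called positive stood at a median of 1.40% in the ICM, 1.18% in the TE, 2.98% in the epiblast and 23.4% in the ExE. Those called negative went from 10.3% in the ICM to 84.0% in the epiblast and from 11.3% in the TE to 52.3% in the ExE. Leaving out ExE replicate 1 lowered the counts to 874 and 2277, and leaving out ExE replicate 2 lowered the negative count to 2821. Among the 13651 regions below 20% in 8-cell embryos, the ICM and the TE, the difference of differences was called positive in 1084 and negative in 1662. In these early unmethylated regions, a rise was called in both lineages in 2787, only from TE to ExE in 1289 and only from ICM to epiblast in 384. In 9191 no rise was called in either lineage.

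The levels around the regions called higher in the ExE differed from those around regions below 20% in the epiblast with no called difference. These sets were not matched on CpG number or level, and 1402 of the 1646 called regions were below 20% in the epiblast. Of those 1402, 538 had another such region within 10 kb, so that the surroundings can include other called regions. Within the regions called higher in the ExE the mean level was 26.1% ± 0.877 in the ExE and 7.59% ± 0.473 in the epiblast. In the 500 bp before them it was 34.1% ± 1.34 and 20.4% ± 0.63, and at 5 kb it was 37.7% ± 0.588 and 44.2% ± 0.873. Around regions below 20% in the epiblast with no called difference, the level in the 500 bp before them was 16.9% ± 0.752 in the ExE and 27.3% ± 0.407 in the epiblast. At 5 kb it was 53.0% ± 1.37 in the ExE and 68.5% ± 0.329 in the epiblast.

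**Figure D4:**
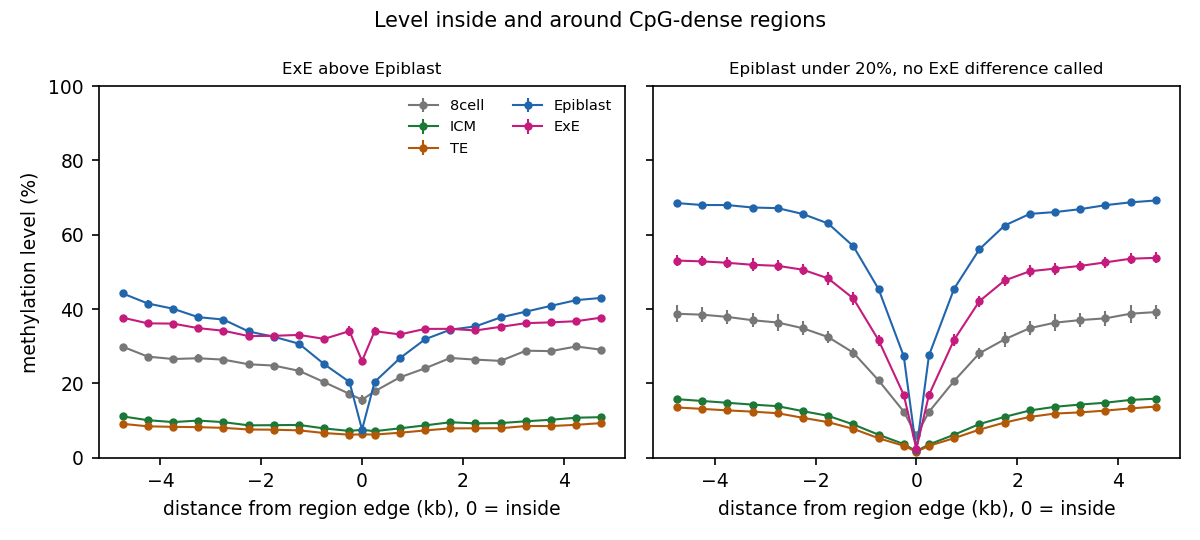
Mean methylation level (y axis, percent) inside CpG-dense regions and in 500 bp steps up to 5 kb on either side (x axis, kb from the region's edge) for the 5 groups, with whiskers for the SD between libraries (n = 2). The left panel shows the regions called higher in the ExE and the right panel those below 20% in the epiblast with no called difference. At 5 kb before the region the epiblast is at 44.2% in the left panel and 68.5% in the right.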

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

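The tests of explanations in this part were chosen after the results were seen; the difference of differences was planned. The change over implantation was called different between the lineages in 1391 and in 4414 CpG-dense regions. In the first, the difference of ExE minus TE lay above that of epiblast minus ICM, and in the second it lay below. Of the first, 1272 were called higher and 8 lower in the ExE than in the TE, and of the second 3653 and 28. With windows of at least 21 CpGs the numbers were 489 and 657. Without ExE replicate 1 they were 874 and 2277, and without ExE replicate 2 the second was 2821.

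The pattern behind the first number is that 1646 CpG-dense regions were higher in the ExE than in the epiblast while most of the genome was lower. Incomplete bisulfite conversion in the ExE libraries would leave unconverted cytosines everywhere, but the mitochondrial level was at most 1.278% in them, and the median level of these regions in the ExE was 24.3%. Cells of another tissue in the ExE samples could raise regions that are methylated in them. If the ExE cells were at the level of the epiblast, a minority of fully methylated cells could give at most 50% plus 0.5 times the epiblast level. In 88 of the 1646 regions the ExE lay above that limit, and in 63 of these both libraries did. Only 3 passed a one-sided test against the limit (adjusted p under 0.05), fewer than the 5 set as needed to exclude the explanation for that part. There were 38 regions above 50% in the ExE with the epiblast below 20%, fewer than the 50 set to exclude the explanation. That count cannot decide, since the limit above lies over 50% wherever the epiblast is methylated at all. Both bounds were set after the levels were seen. Cells of another tissue and a difference of the ExE itself cannot be told apart here, because too few regions decide and the level of another tissue was not measured. A difference between the embryonic and the extraembryonic lineage, which the design names, stays open as a hypothesis.

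Methylated reads at mitochondrial CpGs, which no comparison used, were above the limit that a count of 0 allows in all 10 libraries. Their share was 0.317% and 0.303% in the 8-cell libraries, 0.522% and 0.466% in the ICM, 0.628% and 0.503% in the TE, 1.113% and 1.083% in the epiblast, and 0.987% and 1.278% in the ExE. No biological explanation was tested for the differences between groups.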

How the results depend on the processing

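The alternatives that leave out CpGs above 250 reads or the 8-cell libraries were chosen after seeing the data; the others were planned. No named region changed direction under the alternatives in which it was tested. Of the values for whole comparisons, 196 stayed within 1.5 times the reported count, or within the spread between replicates, and 98 did not. The global level without a replicate always lies within that spread, so those values could not move. For the named regions, 258 values kept the call and 22 lost it. A region that an alternative did not test is in neither count. Most named regions were not tested with the higher minimum of reads and CpGs. The region on chromosome 3 from 127248959 to 127249252 was tested neither there nor with thinned reads. Without a minimum difference no call can be lost. Except where the number of regions tested shows it, the cause of a change was not tested.

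In CpG-dense regions, requiring 50 reads and 5 CpGs left 26970 regions tested. It gave 0 calls for TE minus ICM, 801 regions higher in ExE than in epiblast, and 675 positive and 2655 negative differences of differences. With windows of at least 21 CpGs 16332 regions were tested. The counts were 5532 for ICM minus 8-cell, 6826 for TE minus 8-cell, 0 for TE minus ICM, 7315 for epiblast minus ICM, 6534 for ExE minus TE, 646 higher and 2767 lower for ExE minus epiblast, and 489 positive and 657 negative differences of differences. With windows of at least 12 CpGs 65564 were tested and the counts in that order were 33747, 40255, 4, 51837 and 48937, with 31952 lower in ExE than in epiblast, and 2205 and 14031. Without the 8-cell libraries 52153 were tested, with 5 calls for TE minus ICM, 3128 higher in ExE than in epiblast, and 2737 and 7968 differences of differences. Thinning the reads to the shallowest library left 32867 tested, with 2 calls for TE minus ICM, 1014 higher and 5688 lower in ExE than in epiblast, and 671 and 1587 differences of differences.

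With the number tested unchanged, a minimum difference of 20 points gave 10682 for ICM minus 8-cell, 669 higher and 5649 lower in ExE than in epiblast, and 689 positive differences of differences. No minimum gave 2660 higher in ExE than in epiblast. The spread of the compared groups only gave 0 for TE minus ICM. The mean CpG level with limma gave 0 for TE minus ICM, 7768 lower in ExE than in epiblast, and 912 and 2580 differences of differences.

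For 1 kb tiles, the counts are for ICM minus 8-cell, TE minus 8-cell, TE minus ICM, epiblast minus ICM, ExE minus TE and ExE minus epiblast. They were 209779, 220329, 65, 243437, 230421 and 199487 with 50 reads and 5 CpGs (253261 tested), and 948157, 1042372, 643, 1254891, 1108490 and 1063804 with 10 reads and 2 CpGs (1278052 tested). Thinned reads gave 334699, 357555, 102, 426509, 383555 and 276196 (443028 tested). Leaving out the 8-cell libraries gave 2291, 1667291, 1467956 and 1444402 for the last 4 (1694809 tested). Tiles of 5 kb gave 433403, 111, 453674, 425621 and 409633 for the last 5 (455515 tested). With them, the first bin of density in which the ExE was above the epiblast started at 60 CpGs per kb. For TE minus ICM alone, 20 points gave 165, the spread of the compared groups 785 and limma 0.

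The level weighted by reads was 41.4% in 8-cell embryos, 24.5% in the ICM, 21.5% in the TE, 80.5% in the epiblast and 54.0% in the ExE. The mean over CpGs moved the first 4 to 48.2%, 22.0%, 18.97% and 78.8%. Over CpGs with at least 10 reads it was 53.1% in 8-cell embryos, 20.4% in the TE and 81.0% in the epiblast. Over the CpGs listed in all 10 libraries it was 50.7%, 25.35%, 22.4%, 82.5% and 57.9% in the 5 groups. Without CpGs above 250 reads the weighted level was 49.7% in 8-cell embryos, 23.5% in the ICM and 20.2% in the TE.

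Leaving out each replicate in turn, with the lone library assumed to vary like the other groups, gave 11565 to 15214 CpG-dense regions for ICM minus 8-cell, 15587 to 19038 for TE minus 8-cell, 0 to 2 for TE minus ICM, 24133 to 24635 for epiblast minus ICM and 20866 to 22155 for ExE minus TE. It gave 1361 to 1544 higher and 9040 to 10145 lower for ExE minus epiblast, and 874 to 1348 positive and 2277 to 4395 negative differences of differences. Tiles for TE minus ICM ran from 68 to 620.

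In CpG-dense regions with the replicate number as a block, ExE minus epiblast gave 1639 higher and 13845 lower, and TE minus ICM gave 0. For tiles of TE minus ICM the same block gave 270, against 313 without it. The named regions on chromosome 13 for TE minus ICM (adjusted p = 0.11) and on chromosome 10 for TE minus 8-cell (0.057) were no longer called with the block. Across regions, the deviations of equally numbered replicates correlated most between ICM and TE (0.0564) and between epiblast and ExE (0.0528), the groups dissected from the same stage. Over the other pairs of groups the correlations ran from -0.0191 to 0.0178. The labels do not say that equal numbers mark matched dissections, and these low values do not settle it.

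The count test from another package and the tests of gene lists were planned and not run. The quasi-binomial test recovered 26.0% of simulated differences of 15 points between TE and ICM in CpG-dense regions, so that the near absence of calls there does not exclude differences of that size.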

Other observations

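Apart from the test of sequence variants, all tests in this part were chosen after the results were seen, and the bootstrap bound used in that one was added later. The regions that were higher in the ExE lay close together. Of 12247 CpG-dense regions below 20% in the epiblast, 1402 were higher in the ExE, and 538 of these (38.4%) had another such region within 10 kb. When the calls were relabelled at random within chromosomes, a mean of 90.5 did (one-sided permutation p = 0.0001, the smallest that 10000 relabellings can give). Regions within 10 kb can be parts of the same stretch. At distances between 10 and 50 kb, 400 had such a neighbour, against a relabelled mean of 216 and a highest value of 286. Of all 1646 regions higher in the ExE, the 1 Mb windows with the most were chromosome 5 from 120000001 to 121000000 with 21 of 39 tested, chromosome 15 from 102000001 to 103000000 with 20 of 49, and chromosome 11 from 96000001 to 97000000 with 17 of 56. Over the 21 called regions of the first window, the median level was 35.1% in the ExE, 2.71% in the epiblast and 2.06% in the TE. The ExE and epiblast values follow from the choice of these regions. Another 6 of the 39 were called lower in the ExE.

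Across 23953 autosomal domains of 100 kb the level fell with the number of CpGs in 8-cell embryos, the ICM, the TE and the epiblast, with Pearson's r of -0.304, -0.312, -0.326 and -0.385, and rose with it in the ExE, with r of 0.481. Spearman's rho was -0.28, -0.323, -0.345, -0.191 and 0.608. The domains are not independent replicates. Pearson's r in the single ExE libraries was 0.473 and 0.487. The range from the 10th to the 90th percentile of domains was 35.7 points in 8-cell embryos, 25.2 in the ICM, 21.9 in the TE, 13.1 in the epiblast and 26.4 in the ExE.

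On chromosome X the level was 49.7% ± 1.20 in the ExE, below that of the lowest autosome (chromosome 7, 54.6%). The X holds fewer CpGs per tile, but with autosomal tiles matched on CpG number the difference of X minus autosomes was -5.391 points (SD 0.418) against -7.83 without matching, so that density could account for part of it only. In the epiblast the matched difference had the same sign as in the ExE, at -1.72 ± 0.54 points. In the ICM and the TE it was of the other sign, at 5.24 ± 0.477 and 4.84 ± 0.377 points. More male cells in the ExE samples would lower the depth of the X there. The ratio of X to autosomal reads per CpG was 0.85 ± 0.0767 in the ExE against 0.793 ± 0.0543 in the epiblast. The difference of 0.0565 (SE 0.0664) is too imprecise to exclude a lower ratio in the ExE. In the earlier groups the X was read more deeply than the autosomes in every library. The ratios ran from 1.063 in TE replicate 2 to 1.358 in 8-cell replicate 1. A mix of male and female cells would give at most equal depth, so the ratio cannot decide. Y reads per M autosomal reads were 454.9 and 538.4 in the epiblast libraries and 410.9 and 543.3 in the ExE libraries. The ExE values lay on either side of the epiblast values and cannot decide it either. Inactivation of one X in female cells was not tested, as the labels give no sex.

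The 505 CpG-dense regions that fell from ICM to epiblast went against the direction of most, as 24895 of 37696 were called higher in the epiblast. Chance high values in the ICM libraries would leave the TE, which did not enter the comparison, at the level of the epiblast, but its median there was 19.092% against 3.05% in the epiblast. Sequence variants at single CpGs, possible in embryos of a hybrid strain, would move few CpGs per region, but a median of 83.33% of a region's CpGs were lower in the epiblast (95% bootstrap interval of the median 81.48% to 84.62%). A loss of methylation at these regions remains a hypothesis, and falls were not confined to the lineage to the epiblast. Their median was 44.0% in 8-cell embryos and 9.35% in the ExE. Of the 505, 232 were called lower and 2 higher in the ICM than in 8-cell embryos. From the TE to the ExE, 186 were called lower and 50 higher.

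In 56 CpG-dense regions each of the 5 groups lay between 35% and 65%. Their levels still moved within that range, with 20 called lower in the TE than in 8-cell embryos and 21 called higher in the epiblast than in the ICM. The one with the most CpGs, chosen after its values were seen, was on chromosome 2 from 174123317 to 174126564 with 218 CpGs, at 39.3% ± 3.31 in 8-cell embryos, 54.9% ± 2.21 in the ICM, 41.9% ± 2.13 in the TE, 51.1% ± 10.9 in the epiblast and 54.9% ± 0.685 in the ExE. Another was on chromosome 11 from 11925414 to 11926990 with 158 CpGs, between 43.3% ± 4.58 in the TE and 53.5% ± 0.346 in the epiblast. A further 83 regions lay above 80% in all 5 groups.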
